A study of Solanum tuberosum with 20 samples.

How the data were processed

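RNA from young leaves of potato plants of 2 genotypes, wild type (WT) and plants overexpressing CBF1 of Arabidopsis (CBF1OX), was hybridised to 20 Affymetrix tomato arrays. Per the labels, biotin-labelled cRNA was made from 5 ug of total RNA by the standard Affymetrix protocol and signals were computed with MAS5, whose version, background and scaling settings are not given in the sources used here. The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array, of 10209 probe sets. The 8 arrays of the low temperature experiment share a mean signal between 454.97 and 454.98 and the 8 arrays of the high light experiment one between 575.89 and 575.90. The 4 drought arrays do not: their means were 336.93 and 371.63 in the controls and 235.89 and 275.27 in drought. Array images and probe-level signals were not used here.

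Before the data were examined, the groups, the comparisons, the test, the filter, the alternatives other than centring of arrays, 25 gene lists and the rule for named genes were chosen. The labels put the arrays into 10 groups of 2. Comparisons were made within an experiment, except the effect of CBF1OX without stress, which averages the low temperature and high light experiments.

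The 108 array control and 63 reporter control probe sets were left out of the tests, leaving 10038 probe sets. Signals were transformed as log2(signal + 1), and 6308 probe sets with at least 2 of 20 arrays at or above the median signal of 78.2 were tested. A linear model with 10 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), with 10 residual and 8.4 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Interactions of genotype and stress were contrasts in the same model. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

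The method was tested on simulated data of 6308 probe sets with 200 changed, in 5 simulations. For 2 against 2 arrays it recovered 9.3% of changes of 1.5-fold, 50.7% of 2-fold and 92.1% of 4-fold, and 3.8% of calls were false. For the mean of 4 against 4 control arrays it recovered 36.7%, 79.7% and 98.5%, with 4.4% false calls. For the interaction it recovered 1.5%, 17% and 69.7%, with 2% false calls. The noise was drawn independently for each probe set, without shifts of whole arrays. Far fewer probe sets were changed than passed in the stress comparisons, so these shares need not hold there.

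Gene symbols come from an annotation of the array's tomato sequences. They covered 909 probe sets (9.06%) with 802 symbols, 207 of these probe sets with a LOC symbol, and 0 could be matched to the potato gene table used here. The 25 lists were given as patterns of symbols, which found 166 symbols. On the array's symbols, before any test, 44 symbols were added and 13 removed by hand, and 2 lists were added. For 3 lists the array had 0 symbols (Calvin cycle, circadian clock and tuber), and 18 lists with at least 3 tested probe sets were tested with camera, with a preset correlation of 0.01, against all other probe sets. Camera was repeated with the correlation estimated for each list. As an alternative fry was run, which tests whether a list moves one way on balance and not whether it moves more than other genes. A list count "adjusted over the list alone" uses Benjamini and Hochberg within the list.

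Genes were named by this rule: in the 6 main comparisons, among named probe sets past the threshold whose 2 groups of arrays do not overlap, the 8 largest rises and 8 largest falls, and up to 4 members of each list with the smallest p, or 1 as a value where none passed. In the other comparisons the 5 largest rises and falls were taken, and CBF/DREB genes in every comparison of genotypes. A gene with several probe sets is given by the brightest. List members outside this rule were named after their values were seen, where they make up a count of a list or an overlap.

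The background level of an array was the 95th percentile of 62 reporter probe sets (9.8 to 35.3). Where arrays of the dimmer side of a comparison lay below it and none of the brighter side did, the fold was computed with that level in their place and is a lower bound, in means of 2 experiments and interactions too. Where the median change of all probe sets was beyond 0.1 on the log2 scale, changes are given relative to it. The overlaps of calls were tested with Fisher's exact test, with 44 tests in 11 pairs adjusted together by Benjamini and Hochberg. Correlations run across 6308 probe sets.

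Alternatives were quantile normalization, an offset of 16 before log2, no filter, a stricter filter, a fit of the arrays of the experiment alone, a fit with the replicate letter as a block, each array left out in turn, and, added after the data were seen, arrays centred on their median.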

Results

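Transcript levels were measured in young leaves of potato (Solanum tuberosum cv. Désirée), in wild type (WT) plants and in plants that overexpress CBF1 of Arabidopsis (labelled AtCBF1OX, here CBF1OX). CBF1 is a transcription factor of the AP2/ERF family that activates cold-regulated genes. The 20 arrays form 10 groups of 2 arrays and come from 3 experiments. In the low temperature experiment (8 arrays), WT and CBF1OX plants were kept at 22 °C or moved to 4 °C. In the high light experiment (8 arrays), both genotypes stayed at 50 or were moved to 800 micromoles of photons per square metre and second. The drought experiment (4 arrays) compared watered WT plants with WT plants whose irrigation was stopped. The length of the treatments is not given in the sources used here, and the labels do not say whether the 2 arrays of a group came from separate plants. The p-values therefore measure only the spread between these arrays.

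The array carries tomato sequences, on which potato RNA was hybridised. Of 10038 probe sets without controls, 909 had 1 tomato gene symbol, 0 had several and 9129 were unnamed here. Symbols below are those of tomato genes, a gene with several probe sets is given by the brightest, and no position in the potato genome is given. The test covered 6308 probe sets, 608 of them named. Mean signal per array was between 454.97 and 454.98 in the low temperature experiment, 575.89 and 575.90 in the high light experiment and 235.89 and 371.63 in the drought experiment. Within a group, log2 signals of the 2 arrays correlated across probe sets, which are not independent replicates, with Pearson's r from 0.9657 to 0.9823. The number of arrays limits the precision: the median SE of a change between 2 groups of 2 arrays was 0.27 on the log2 scale.

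In the text, changes are log2 differences ± SE with n = 2 arrays per group, unless another n is given, and adjusted p-values cover all probe sets tested. "Rose" and "fell" are used of probe sets with an adjusted p under 0.05. Where arrays of the dimmer side lay below the background level, the change is given as "at least N-fold", computed against that level and not relative to other probe sets; this was 1 of 2 arrays for exp11 in drought, for ERF4, XTH6 and Wiv-1 in WT high light and for CHS1 in CBF1OX high light, and 1 of the WT control arrays for RAN2A. List counts are given over all probe sets tested and adjusted over the list alone. Most genes given with a value kept their call under every alternative run, and exceptions are stated for many, not all, of the named genes. None of the 27 calls of gene lists by camera (a test of a list against all other genes) held with an estimated in place of a preset correlation between genes: 0 lists passed, so those calls do not reach beyond the listed genes.

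The drought comparison asks which transcripts differ between WT plants without and with irrigation. The median of all probe sets was lower by a log2 change of -0.31 on the drought arrays, and the changes below are relative to it, while p-values belong to the changes as measured. The largest fall among named genes was that of Dea1, by a log2 change of -5.61 ± 0.51 (adjusted p = 2.07e-08). Genes of cell wall loosening were among those that fell most: the expansin EXP2 by -4.48 ± 0.21 (adjusted p = 1.86e-11), the xyloglucan endotransglucosylase/hydrolase XTH1 by -3.56 ± 0.40 and the expansin exp11 at least 7.76-fold. All 6 probe sets of cytosolic ribosomal proteins fell, among them RPL37 (-2.90 ± 0.32), RPL8 (-2.28 ± 0.15) and RPL3 (-2.10 ± 0.15). AgpL1, a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, rose by 3.10 ± 0.28 (adjusted p = 1.27e-07), and the sucrose synthase sus3 rose by 2.91 ± 0.39 (adjusted p = 2.21e-05). AREB1, a bZIP factor of abscisic acid responses, rose by 2.71 ± 0.33 (adjusted p = 7.42e-06).

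Of 31 cell wall probe sets in drought, 17 fell, 2 rose and 12 did not pass. Of all 6308 probe sets 2211 fell, and camera's 4 calls in drought were for other lists. Adjusted over the list alone, 17 fell and 3 rose, and after quantile normalization 13 fell and 4 rose. The pectin methylesterase PMEU1 fell by a relative change of -2.41 ± 0.20 and the expansin EXP5 by -2.43 ± 0.25. The ribosomal list kept 6 lower probe sets after quantile normalization and over the list alone; its median was -1.99 relative to all probe sets (camera adjusted p = 0.000837; adjusted p = 0.338 with an estimated correlation). Of 10 probe sets of starch and sucrose metabolism, 6 rose and 2 fell, as also over the list alone, with a relative median of 1.85 (camera adjusted p = 0.00453; adjusted p = 0.184 with an estimated correlation). Sucrose-phosphate synthase SPS rose by 1.77 ± 0.20 and the ADP-glucose pyrophosphorylase subunit AGPL3 fell, at -0.82 relative to all probe sets. The 3 phenylpropanoid probe sets all rose over all probe sets and adjusted over the list alone (camera adjusted p = 0.0266; adjusted p = 0.498 with an estimated correlation). They were the chalcone synthases CHS1 and CHS2 of flavonoid synthesis and hqt of chlorogenic acid synthesis, the last with a relative change of 1.81 ± 0.30 (adjusted p = 0.000426). The call of CHS1 was lost without control array B or either drought array (highest adjusted p = 0.222).

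In the list of raffinose, proline and polyamine synthesis, 6 of 8 probe sets fell in drought (7 adjusted over the list alone). These measured ornithine decarboxylase ODC (relative change -2.07 ± 0.31), the arginine decarboxylases adc1 and ADC, and the proline synthesis gene PRO2; the list's only probe set of raffinose synthesis, GolS-1, was too dim to be tested. Of 8 pathogenesis-related probe sets 5 fell, and 8 when adjusted over the list alone, with PR-5 at -1.74 ± 0.39 and the chitinase CHI9 at -1.50 ± 0.28. In these lists camera gave adjusted p = 0.128 for both. Antioxidant enzymes went both ways, 2 higher and 6 lower of 14 (also over the list alone), and 5 higher and 3 lower after quantile normalization. The iron superoxide dismutase FESOD fell by a relative change of -2.03 ± 0.26 and monodehydroascorbate reductase MDHAR by -1.32 ± 0.24, while the glutathione peroxidase GPXle-1 rose by 1.68 ± 0.24. Of 16 probe sets of ethylene synthesis and ERF factors 4 rose, and 0 when adjusted over the list alone (camera adjusted p = 0.0296; adjusted p = 0.591 with an estimated correlation).

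Markers of dividing cells were lower in drought in 5 of 11 probe sets (6 adjusted over the list alone), and 4 were lower and 2 higher after quantile normalization. Among them PCNA fell by a relative change of -1.18 ± 0.23 and the cyclin CYCD3 by -1.13 ± 0.28. Heat shock proteins and chaperones had 1 higher and 2 lower of 5, with the chaperonin CPN21 at -2.02 ± 0.26; the median of that list was -0.38 as measured and 0.32 after quantile normalization. Of 5 photosystem probe sets 4 were lower as measured, but their relative median was -0.05 and after quantile normalization 1 was lower. Light-harvesting proteins and markers of senescence had 0 of 3 and 0 of 4 past the test, and among the chlorophyll-binding proteins CAB6A changed by -0.18 as measured (adjusted p = 0.376). Of the LEA-type proteins, which accumulate in dry or cold tissue, 0 of 2 passed, and ER5 stood at 0.54 as measured (adjusted p = 0.325). Smaller lists had 3 lower of 11 for jasmonate, 1 higher and 1 lower each of 4 for lipids and of 3 for vein or stem, 1 lower of 2 for gibberellin, and 1 higher of 2 for photoprotection. That last probe set was zeaxanthin epoxidase ZEP of the xanthophyll cycle, with a relative change of 1.48 ± 0.26.

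By limma, 2832 of 6308 probe sets passed in drought, 621 higher and 2211 lower (21.9% higher). After quantile normalization 1497 were higher and 1527 lower (49.5% higher), so the split between directions depends on the scaling. With 1 array left out, between 2239 and 2570 passed. The median 3' minus 5' difference of 6 probe pairs, a sign of RNA quality, was higher by 0.06 on the drought arrays. In 6 of the 18 lists tested the median, the mean and camera's direction differed in sign, as for lipids with a median of -0.71 and a mean of -0.01 against a direction of up.

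**Figure D1:**
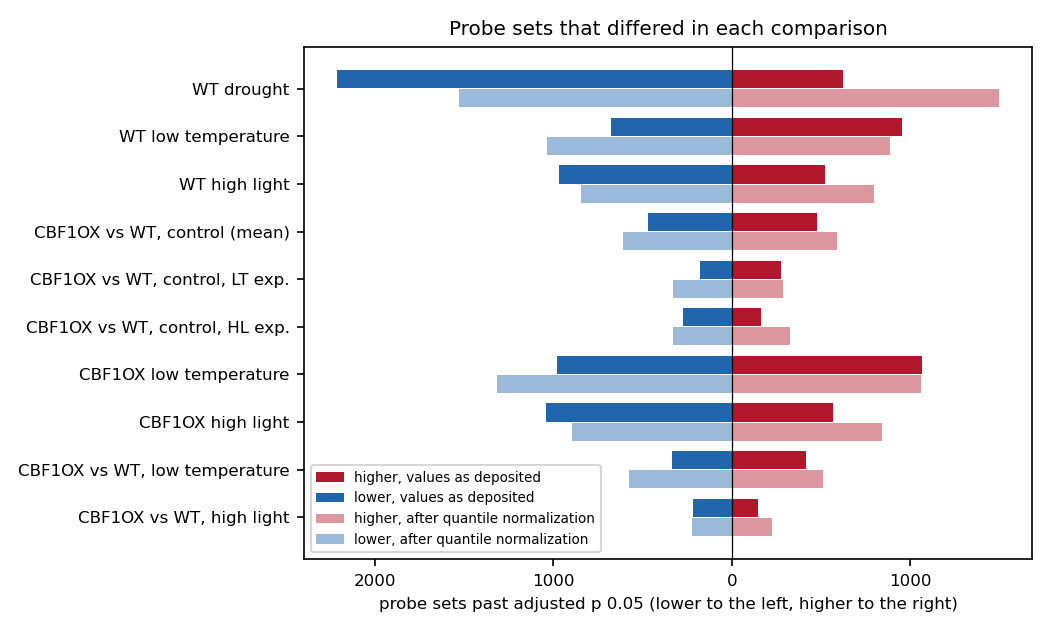
Number of probe sets (horizontal axis) that passed limma's test in each of 10 comparisons, bars to the right for higher and to the left for lower; dark bars use signals as deposited and pale bars signals after quantile normalization. In WT drought 621 were higher and 2211 lower as deposited, and 1497 and 1527 after quantile normalization.

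The low temperature comparison asks which transcripts differ between WT leaves at 4 °C and at 22 °C. The largest rise among named genes was that of the glucosyltransferase twi1, 65.3-fold (log2 6.03 ± 0.38, adjusted p = 2.66e-09). The chlorogenic acid gene hqt rose 20.8-fold (log2 4.38 ± 0.30, adjusted p = 8.6e-09), adc1 by 3.21 ± 0.29 (adjusted p = 2.25e-07) and sus3 by 3.19 ± 0.39 (adjusted p = 7.52e-06). The LEA-type genes ER5 and LEA14 both rose, ER5 at least 1.99-fold (adjusted p = 9.53e-05) and LEA14 by 1.87 ± 0.25 (adjusted p = 2.23e-05). DREB3, the tested member of the CBF/DREB family, rose by 1.34 ± 0.25 (adjusted p = 0.000554). The factor ERF4 fell by -3.28 ± 0.39 (adjusted p = 5.3e-06) and POR2 by -2.53 ± 0.20 (adjusted p = 3.73e-08).

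All 3 phenylpropanoid probe sets rose at 4 °C, over all probe sets and adjusted over the list alone, with a median of 2.95 (camera adjusted p = 0.00754; adjusted p = 0.294 with an estimated correlation). Among 10 probe sets of starch and sucrose metabolism 5 rose and 1 fell (6 and 1 adjusted over the list alone), including all 3 of the beta-amylase BMY3, whose brightest rose by 3.15 ± 0.51. Of 8 probe sets of raffinose, proline and polyamine synthesis 4 rose, also over the list alone, and these were 3 of adc1 and 1 of ODC. The call of ODC was lost without any single array (highest adjusted p = 0.252) and after quantile normalization, and that of CHS2 without array A of either group (highest adjusted p = 0.231). Camera gave adjusted p = 0.00754 for both lists, and adjusted p = 0.294 with an estimated correlation. Cell wall genes fell in 11 and rose in 3 of 31 probe sets, as also over the list alone, with the same pair of p-values. The beta-galactosidase TBG3 fell by -2.31 ± 0.32, XTH16 by -1.70 ± 0.27 and EXP2 by -1.38 ± 0.21, while the expansin EXPA4 rose by 2.40 ± 0.27.

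Of 16 ethylene and ERF probe sets 8 rose and 2 fell at 4 °C (9 and 3 adjusted over the list alone; camera adjusted p = 0.121), among them the receptor ETR4 at 2.28 ± 0.35 and the factor JERF3 at 1.77 ± 0.25. Jasmonate genes rose in 4 of 11 probe sets (6 adjusted over the list alone, 2 after quantile normalization), with allene oxide synthase AOS at least 3.32-fold higher (adjusted p = 4.22e-05). Antioxidant enzymes rose in 4 of 14 probe sets, also over the list alone: both probe sets of the ascorbate peroxidase APX2, of which 1 rose by 0.92 ± 0.12, the catalase CAT2 (0.91 ± 0.12) and GPXle-1 (1.75 ± 0.24). The median of that list was -0.08, its mean 0.25 and camera's direction up. The heat shock gene Hsp90-1 rose by 2.52 ± 0.33 and the omega-3 desaturase Fad7 by 1.21 ± 0.17, in lists with 2 of 5 and 1 of 4 higher. AREB1 rose by 2.06 ± 0.33, and violaxanthin de-epoxidase VDE fell by -0.86 ± 0.21. Light-harvesting, photosystem, senescence, vein or stem and gibberellin lists had 0 probe sets past the test, pathogenesis-related proteins 1 higher of 8, ribosomal proteins 1 higher of 6 and dividing cells 2 lower of 11.

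By limma, 1630 probe sets passed at 4 °C, 954 higher and 676 lower (58.5% higher), against 884 higher and 1035 lower after quantile normalization (46.1%). Without WT control array B of that experiment 925 passed, and the highest count with 1 array left out was 1219. The 3' minus 5' difference was lower by a median of -0.30 at 4 °C, and hybridisation spike-ins by -0.30.

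The high light comparison asks which transcripts differ between WT leaves under 800 and under 50 micromoles per square metre and second. The median of all probe sets changed by -0.14, and changes are again given relative to it, with p-values of the changes as measured. The chalcone synthase CHS1 rose at least 9.1-fold (adjusted p = 7.84e-07) and CHS2 by a relative log2 change of 4.80 ± 0.40 (adjusted p = 1.54e-07). HMGR of the mevalonate pathway rose by 3.12 ± 0.29 (adjusted p = 7.84e-07) and FESOD by 2.47 ± 0.26 (adjusted p = 3.69e-06). ERF4 fell at least 20.3-fold (adjusted p = 6.62e-08), SIP by -4.79 ± 0.26 (adjusted p = 2.55e-10) and the EIN3-like factor EIL3 by -2.79 ± 0.27. The chlorophyll-binding protein genes CAB5 and CAB4 fell, with relative changes of -2.11 ± 0.40 (adjusted p = 0.000382) and -0.97 ± 0.19 (adjusted p = 0.000263).

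All 3 phenylpropanoid probe sets rose in high light, also adjusted over the list alone, with a relative median of 4.80 (camera adjusted p = 2.82e-05; adjusted p = 0.0927 with an estimated correlation). Antioxidant enzymes rose in 8 and fell in 1 of 14 probe sets, as also adjusted over the list alone, with a relative median of 0.79 (camera adjusted p = 7.08e-05; adjusted p = 0.0927 with an estimated correlation). Examples besides FESOD were APX2 at 1.25 ± 0.12, the dehydroascorbate reductase DHAR2 at 0.96 ± 0.18 and CAT2 at 0.78 ± 0.12. Ethylene and ERF genes fell in 8 of 16 probe sets, also over the list alone, with a relative median of -0.76 (camera adjusted p = 9.83e-05; adjusted p = 0.157 with an estimated correlation). JERF1 fell by -2.04 ± 0.19 and the ACC oxidase ACO6, the enzyme of the last step of ethylene synthesis, by -1.63 ± 0.23. ERF3, also counted as a fall, lay below background on all arrays of both groups, so its size cannot be read.

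Light-harvesting proteins fell in 2 of 3 probe sets in high light, also over the list alone (camera adjusted p = 0.0952), and 0 of 5 photosystem probe sets passed. Pathogenesis-related proteins fell in 5 of 8 probe sets (2 after quantile normalization), with CHI9 at a relative change of -1.91 ± 0.28. CHI14, NP24-I and GluB lay below background on both high light arrays, so they were at least 1.76-, 1.78- and 1.82-fold lower. PR-P2 lay below it on 1 and was at least 2.02-fold lower. Cell wall genes went both ways, 4 higher and 8 lower of 31 (4 and 9 adjusted over the list alone): XTH6 rose at least 5.61-fold, and TBG3 and EXP2 fell by -2.41 ± 0.32 and -2.14 ± 0.21. Both LEA-type genes fell, ER5 by -2.17 ± 0.43 (adjusted p = 0.000631), but the call of LEA14 was lost after quantile normalization (adjusted p = 0.0572) and without either control array or high light array A (highest adjusted p = 0.431). DREB3 fell by -0.93 as measured (adjusted p = 0.0106), a call lost without control array A or high light array B (highest adjusted p = 0.13). Hsp90-1 and CPN21 rose by 1.68 ± 0.33 and 1.57 ± 0.26, 2 of 5 in their list. Other lists had 1 higher probe set each of 8 for polyamines, 11 for jasmonate, 4 for lipids, 6 for ribosomal proteins, 11 for dividing cells, 4 for senescence, 3 for vein or stem and 2 for photoprotection. Starch and sucrose metabolism had 2 higher and 1 lower of 10, the last the cell wall invertase Wiv-1, at least 4.38-fold lower. The glutathione S-transferase GST-T4 lay below background on both high light arrays and was at least 1.24-fold lower (adjusted p = 0.0139). That call was lost without control array B or high light array B.

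By limma, 1492 probe sets passed in WT high light, 522 higher and 970 lower (35% higher), against 799 higher and 848 lower after quantile normalization (48.5%) and 1043 higher and 737 lower with arrays centred on their median (58.6%), so the balance between directions depends on the scaling. Without WT high light array A 839 passed, and without WT control array A of that experiment 842. The 3' minus 5' difference changed by a median of -0.05.

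**Figure D2:**
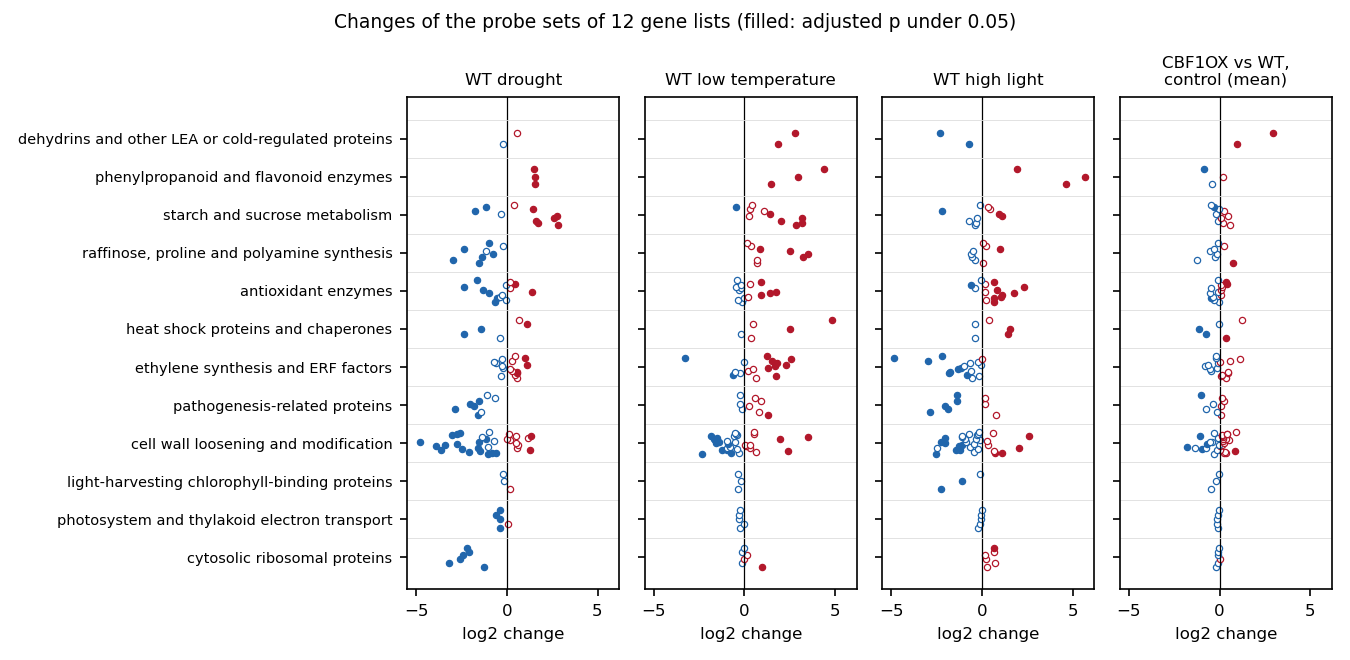
Log2 change (horizontal axis) of each probe set of 12 gene lists in WT drought, WT low temperature, WT high light and CBF1OX against WT without stress; points are probe sets, filled where the adjusted p was under 0.05. All 6 ribosomal protein probe sets lay below 0 in drought, and all 3 phenylpropanoid probe sets above 0 in the 3 stresses.

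The 3 stresses were compared in WT plants by counting probe sets that passed in the same direction. Higher in all 3 stresses were 29 probe sets, where 7.8 would be expected if the responses were independent, and 63 against 26.6 after quantile normalization. They included CHS1, CHS2, hqt, CCD1A, TMT and ail. Lower in all 3 were 51 against 36.4 expected (37 against 33.7 after quantile normalization), including EXP2, exp11, LePIP1 and the subtilisin-like protease gene sbt4a. TBG3, POR2 and CRTL-E-1 were also lower in all 3, though not after quantile normalization. Of all these only hqt, TMT, EXP2 and LePIP1 kept all 3 calls under every alternative; the highest adjusted p was 0.154 for ail, 0.146 for exp11, 0.146 for CCD1A and 0.189 for sbt4a. Without WT control array A of the high light experiment the total fell from 80 to 53.

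Pairs of responses were compared across genes, which are not independent replicates, with Fisher's exact test (two-sided) on the overlaps; 44 such tests were made in 11 pairs of comparisons and their p-values adjusted together. Low temperature and high light shared 151 higher probe sets (78.9 expected; Fisher's exact p = 2.81e-17, adjusted 8.24e-17) and 206 lower ones (104 expected; Fisher's exact p = 3.84e-26, adjusted 1.3e-25), with Pearson's r = 0.215. Low temperature and drought shared 147 higher ones (93.9 expected; Fisher's exact p = 2.9e-09, adjusted 7.51e-09) but 234 lower ones against 236.9 expected (Fisher's exact p = 0.831, adjusted 0.871), with r = 0.067; 95 were lower at 4 °C and higher in drought (66.5 expected; Fisher's exact p = 0.000212, adjusted 0.000491), and 308 the reverse (334.4 expected; Fisher's exact p = 0.0554, adjusted 0.0863). High light and drought went in opposite directions more often than expected: 212 were lower in high light and higher in drought (95.5 expected; Fisher's exact p = 5.21e-35, adjusted 1.91e-34), and 291 the reverse (183 expected; Fisher's exact p = 7.78e-24, adjusted 2.45e-23), with r = -0.247. FESOD, CPN21 and DHAR2 were among those higher in high light and lower in drought.

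The comparison of CBF1OX with WT plants without stress asks which transcripts differ between the genotypes. None of the 10 groups held transformed plants without the factor, so its effect cannot be separated from other differences between the plants. The comparison averages the control plants of the low temperature and high light experiments, 4 arrays per genotype. Its SE comes from the spread between arrays within groups and leaves out how far the 2 experiments disagree. The WT controls of the 2 experiments differed, though their labelled temperature and light were the same. ER5 signals were 1.6 and 7.1 in the low temperature experiment, against 226.3 and 291.1 in the high light experiment. CHS1 went the other way, with 107.2 and 179.5 against 2.6 and 6. ER5 was at least 4.14-fold higher in CBF1OX (n = 4, adjusted p = 2.04e-06; 2 of 4 WT arrays below background), and the second LEA-type gene, LEA14, 1.95-fold higher (log2 0.96 ± 0.18, n = 4, adjusted p = 0.0012). ODD was 8.53-fold higher (log2 3.09 ± 0.20, n = 4, adjusted p = 5.27e-09), the Ran GTPase gene RAN2A at least 3.61-fold and the calcium-dependent protein kinase CDPK1 higher by 1.05 ± 0.24. Lower in CBF1OX were sbt4a (-1.90 ± 0.17, adjusted p = 4.71e-07), the EIN3-like factor EIL1 (-1.69 ± 0.18, adjusted p = 4.4e-06) and the plasma membrane proton pump LHA2 (-1.45 ± 0.16, adjusted p = 5.6e-06). The experiments were unequal for sbt4a, which stood at -3.02 in the high light experiment alone. DREB3 stood at 0.34 ± 0.17 (adjusted p = 0.226). The array's probe sets for CBF1, DREB1 and DREB2 of tomato and for the dehydrin TAS14 were too dim to be tested, with signals of at most 97.2, 25.4, 126.7 and 141.8.

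The LEA list, with 2 of 2 probe sets higher over all probe sets and adjusted over the list alone, had too few members for camera. In the 18 lists tested camera made 0 calls for this comparison, with a lowest p of 0.596. Single members passed: AOS (adjusted p = 0.00342), with arrays of both genotypes below background and so no fold, in a jasmonate list with 2 higher of 11, and the superoxide dismutase SODCC.1 at 0.39 ± 0.09, in an antioxidant list with 2 higher and 1 lower of 14. Cell wall genes had 1 higher and 4 lower of 31, also over the list alone, with EXPA4 at 0.88 ± 0.19 and exp18 at -0.96 ± 0.23. Of 5 heat shock genes 1 was higher and 2 lower, with Hsp90-1 at -1.13 ± 0.23. Of 11 markers of dividing cells 2 were lower, with PCNA at -0.76 ± 0.16, and of 3 markers of vein or stem 1 was lower, CCR1 at -0.86 ± 0.20. The lists of ribosomal proteins, photosystem, light-harvesting, lipids and senescence had 0 probe sets past the test. By limma, 944 probe sets passed, 475 higher and 469 lower (591 and 612 after quantile normalization), 126 and 137 of the 944 at least 2-fold.

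The genotypes also differed within each experiment's control plants. In the low temperature experiment ER5 was at least 6.23-fold higher in CBF1OX, ODD higher by 3.48 and the 14-3-3 gene TFT6 by 2.16, and LHA2 lower at -1.44; 273 probe sets were higher and 178 lower (286 and 330 after quantile normalization). In the high light experiment ODD was higher by 2.71, RAN2A at least 3.99-fold, and sbt4a and EIL1 lower at -3.02 and -2.02; 165 were higher and 272 lower (327 and 330 after quantile normalization). The same direction passed in both experiments for 81 higher probe sets (7.1 expected; Fisher's exact p = 2.11e-69, adjusted 1.33e-68) and 91 lower ones (7.7 expected; Fisher's exact p = 7.11e-81, adjusted 6.26e-80), with 0 in opposite directions and r = 0.565 across genes. Each count rests on 4 arrays and dropped when 1 was left out. In the low temperature experiment 451 fell to 263 without WT array A, 166 without WT array B, 189 without CBF1OX array A and 275 without CBF1OX array B. In the high light experiment 437 fell to 232 without WT array A, 156 without WT array B, 195 without CBF1OX array A and 182 without CBF1OX array B.

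Whether the genotypes differ without stress in genes of the WT cold response was asked with the controls of the high light experiment, which share no array with the cold comparison. Their WT levels were not those of the low temperature experiment. LEA14 signals were 1165.3 and 1215.8 in these WT controls, 342.4 and 261.9 in the other ones and 895.9 and 1347.5 in WT at 4 °C. Higher both in unstressed CBF1OX and in WT at 4 °C were 43 probe sets (25 expected; Fisher's exact p = 0.000234, adjusted 0.000515). The 8 named ones were ODD, NAC1, ER5 and LEA14, with CBF1OX effects of 2.71, 1.18, 1.46 and 1.26, CAT2, SAM3 and CCD1A with smaller ones of 0.47, 0.53 and 0.62, and LOC543899, at least 1.38-fold higher. Of these only ODD kept its CBF1OX call in every fit with 1 array left out; the highest adjusted p was 0.205 for NAC1, 0.303 for ER5, 0.086 for LEA14, 0.217 for CAT2, 0.172 for SAM3, 0.346 for CCD1A and 0.542 for LOC543899. The call of CCD1A at 4 °C was lost too (highest adjusted p = 0.146). Lower in both were 34 (29.1 expected; Fisher's exact p = 0.317, adjusted 0.41), including EXP2, EXP5, sbt4a, THOX2 and PDF1B; without single arrays only sbt4a kept its CBF1OX call, and it lost that at 4 °C (highest adjusted p = 0.108). After quantile normalization 81 probe sets were higher in both (45.8 expected) and 71 lower in both (54.1 expected), with 88 in opposite directions (99.9 expected). The size of the lower overlap thus depends on the scaling. Across all 6308 probe sets the effects were nearly unrelated, with Pearson's r = 0.088 and Spearman's rho = 0.063 across genes. With single arrays r ran from -0.012 to 0.172. The reverse arrangement set the controls of the low temperature experiment against the WT high light response, with r = -0.11. In it 40 probe sets were lower in CBF1OX and higher in high light (14.7 expected, Fisher's exact p = 2.73e-09, adjusted 7.51e-09). The opposite held for 50 (42 expected, Fisher's exact p = 0.17, adjusted 0.234). Higher in both were 26 (22.6 expected, Fisher's exact p = 0.432, adjusted 0.514) and lower in both 18 (27.4 expected, Fisher's exact p = 0.0569, adjusted 0.0863).

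**Figure D3:**
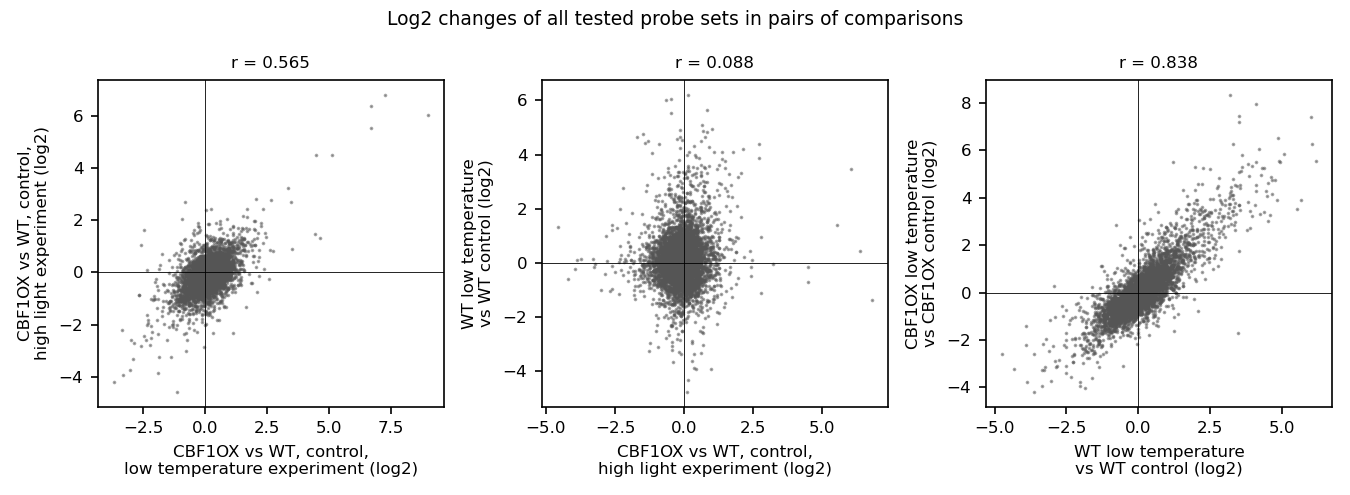
Log2 changes of 6308 probe sets (points) in 3 pairs of comparisons, 1 comparison on each axis. The CBF1OX effects of the 2 control experiments correlated with r = 0.565, the CBF1OX effect and the WT cold response with r = 0.088, and the cold responses of both genotypes with r = 0.838.

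In CBF1OX plants at 4 °C against CBF1OX plants at 22 °C, twi1 rose by 7.43 ± 0.38 (adjusted p = 4.88e-10), hqt by 5.24 ± 0.30 (adjusted p = 5.94e-10), sus3 by 4.19 ± 0.39 and adc1 by 3.72 ± 0.29. LEA14 rose by 2.62 ± 0.25 (adjusted p = 2.64e-07) and DREB3 by 2.16 ± 0.25 (adjusted p = 2.12e-06). POR2 fell by -3.39 ± 0.20, the brassinosteroid oxidase CYP85A1 by -2.44 ± 0.38 and the gibberellin oxidase GA20OX1 by -1.85 ± 0.26. Polyamine genes rose in 6 of 8 probe sets (camera adjusted p = 7.64e-05; adjusted p = 0.144 with an estimated correlation), and pathogenesis-related proteins in 4 of 8 (camera adjusted p = 0.0198; adjusted p = 0.503 with an estimated correlation), with the chitinase CHI3 at 2.93 ± 0.35. Cell wall genes fell in 17 and rose in 3 of 31 (18 and 3 adjusted over the list alone; camera adjusted p = 0.00127; adjusted p = 0.188 with an estimated correlation). Starch and sucrose genes rose in 6 and fell in 1 of 10 (camera adjusted p = 0.00521; adjusted p = 0.144 with an estimated correlation). Phenylpropanoid genes rose in 2 of 3 (camera adjusted p = 0.00787; adjusted p = 0.271 with an estimated correlation), and ethylene and ERF genes rose in 10 and fell in 4 of 16 (camera adjusted p = 0.0214; adjusted p = 0.486 with an estimated correlation).

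By limma, 1064 probe sets were higher and 981 lower in cold CBF1OX plants (52% higher), against 1063 and 1317 after quantile normalization (44.7%), so the balance between directions depends on the scaling. The cold responses of the genotypes shared 701 higher and 498 lower probe sets (160.9 and 105.1 expected), with r = 0.838 across genes. The difference between the responses was tested as an interaction: 6 probe sets passed (2 higher and 4 lower) and 565 had an unadjusted p under 0.05. The count depends on the processing: 42 passed after quantile normalization (30 higher and 12 lower), 45 with an offset of 16, 28 with the arrays of the experiment alone and 3 without a filter. The named one was the hexose transporter HT2, which rose by 2.85 in CBF1OX and lay below background on both WT arrays at 4 °C, a difference of at least 3.34 on the log2 scale (adjusted p = 0.0298). That call held without WT control array B or WT low temperature array A, and was lost without any of the other 6 arrays (highest adjusted p = 0.103). The count was 11 without WT low temperature array A, 1 without CBF1OX control array B and 2 without CBF1OX low temperature array A. DREB3 gave an interaction of 0.82 ± 0.35 (adjusted p = 0.471). In the polyamine and the pathogenesis-related lists 0 probe sets passed over all and 3 of 8 each were higher adjusted over the list alone (camera adjusted p = 0.00223; adjusted p = 0.701 with an estimated correlation, for both).

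Under stress at 4 °C, CBF1OX differed from WT in 417 higher and 334 lower probe sets (509 and 577 after quantile normalization, so the balance turned). HT2 was at least 8.3-fold higher (adjusted p = 7.28e-05), ER5 higher by 2.78 ± 0.43 and DREB3 2.34-fold higher (log2 1.23 ± 0.25, adjusted p = 0.00349). LHA2, the arabinogalactan protein AGP-1 and GA20OX1 were lower at -1.90 ± 0.23, -1.93 ± 0.23 and -1.60 ± 0.26. Pathogenesis-related proteins were higher in 3 of 8 probe sets (4 adjusted over the list alone; camera adjusted p = 0.0179; adjusted p = 0.796 with an estimated correlation), and LEA-type proteins in 2 of 2. The total of 751 fell to 266 without CBF1OX low temperature array B, 466 without array A of that group and 394 without WT low temperature array B.

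In CBF1OX plants under high light against CBF1OX controls the median of all probe sets changed by -0.13, and changes are relative to it. CHS2 rose by 4.92 ± 0.40 (adjusted p = 9.32e-08), CHS1 at least 13.7-fold, AgpL1 by 3.54 ± 0.28 (adjusted p = 6.41e-08) and HMGR by 3.46 ± 0.29. ERF4 fell by -4.38 ± 0.39, SIP by -3.90 ± 0.26, EIL3 by -2.94 ± 0.27 and ER5 by -2.34 ± 0.43. Phenylpropanoid genes rose in 3 of 3 (camera adjusted p = 2.8e-05; adjusted p = 0.156 with an estimated correlation). Antioxidant genes rose in 8 and fell in 2 of 14 (8 and 3 adjusted over the list alone; camera adjusted p = 0.00048; adjusted p = 0.175 with an estimated correlation). Ethylene and ERF genes fell in 8 of 16 (9 adjusted over the list alone; camera adjusted p = 0.000233; adjusted p = 0.175 with an estimated correlation), and both LEA-type genes fell, LEA14 not without CBF1OX control array B (adjusted p = 0.0559). By limma, 567 probe sets were higher and 1042 lower, against 841 and 898 after quantile normalization and 1085 and 802 with arrays centred on their median, which turned the balance. Of 1609, 880 passed without CBF1OX control array B, 898 without CBF1OX high light array B and 1058 without CBF1OX high light array A.

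The high light responses of the genotypes shared 358 higher and 674 lower probe sets (46.9 and 160.2 expected), with r = 0.841 across genes. The interaction passed in 2 probe sets, with 254 at an unadjusted p under 0.05. The named one was AgpL1, with 1.09 in WT (a call lost without control array B or high light array B, highest adjusted p = 0.099) and 3.41 in CBF1OX, a difference of 2.32 ± 0.39 (adjusted p = 0.0355). The call of the interaction held without WT high light array B, was lost without any of the other 7 arrays, and was lost after quantile normalization (adjusted p = 0.106). The count was 5 without WT high light array A, 4 without WT high light array B, and 0 without WT control array B, either CBF1OX control array or CBF1OX high light array A. Of 3 light-harvesting probe sets 0 passed the interaction over all and 2 were higher adjusted over the list alone (camera adjusted p = 0.0163, 0.0745 after quantile normalization; adjusted p = 0.535 with an estimated correlation). Under high light, 145 probe sets were higher and 216 lower in CBF1OX than in WT (226 and 221 after quantile normalization). AgpL1 and ODD were higher by 2.51 ± 0.28 and 1.74 ± 0.29, and LHA2 and sbt4a lower at -2.05 ± 0.23 and -2.03 ± 0.25, while DREB3 stood at 0.09 ± 0.25 (adjusted p = 0.902). Those 361 fell to 124 without CBF1OX high light array B, 200 without array A of that group and 168 without WT high light array A.

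**Figure D4:**
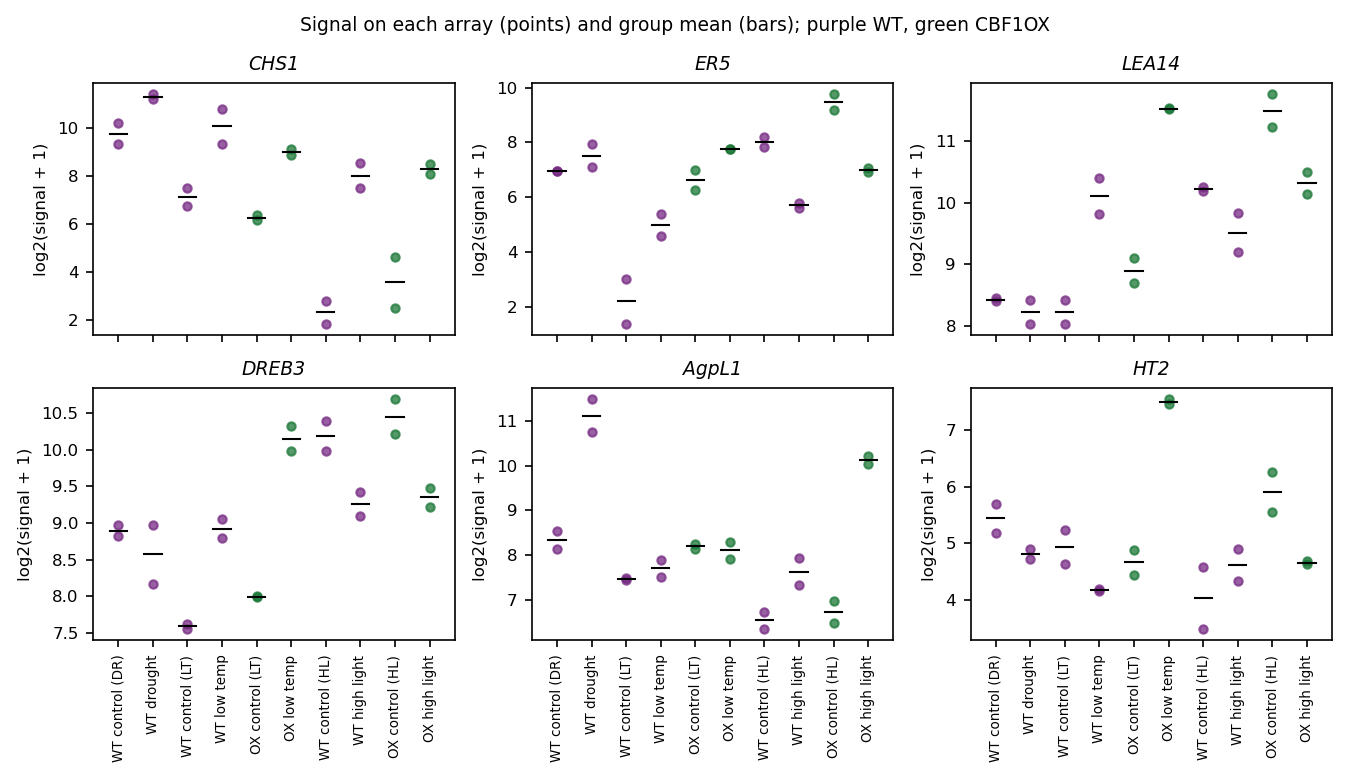
Log2(signal + 1) of CHS1, ER5, LEA14, DREB3, AgpL1 and HT2 on each array (points) with group means (bars) in the 10 groups, WT in purple and CBF1OX in green. ER5 lay higher in CBF1OX than in WT controls of the low temperature experiment, and CHS1 higher in high light than in its controls in both genotypes.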

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

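The tests of array brightness, of labelled plant RNA, of array scaling and of RNA degradation were chosen only after the result was seen; the others were chosen before.

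In WT drought, 21.9% of the probe sets past the threshold were higher. If array brightness alone had lowered the drought arrays, the added spike-ins would have fallen as the plant probe sets did; they changed by -0.07, against -0.31 for the median of all probe sets, but with an SE of 0.219 from the spread between arrays this decides nothing. After each array was centred on its median, 44.9% of calls were higher, which decides nothing either, since centring evens out the directions whatever the cause. Array brightness or less labelled plant RNA on the drought arrays may account for the excess of lower calls, and neither can be told apart from lower levels of many transcripts in dry leaves, because the arrays give no absolute amount of RNA and the spike-ins varied too much between arrays.

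The 6 probe sets of cytosolic ribosomal proteins all fell in drought, with a median of -2.30. A uniform shift of whole arrays as the whole cause is argued against by the median after centring, -1.99 (SD 0.65 among the 6). Centring takes the same amount from every probe set of an array, so it cannot address scaling that differs with brightness. Bright probe sets fell more than dim ones, but only 0.11% of 10000 random lists matched in brightness had a median as low (their middle value -0.62, SD 0.48). Those lists were drawn as independent probe sets, while genes of 1 list can move together. The share may therefore be too low, and brightness is not excluded. RNA degradation would have raised the 3' minus 5' difference, which changed by 0.06 (6 probe pairs), but with an SE of 0.252 from the spread between arrays a rise of 0.5 cannot be ruled out, so RNA degradation cannot be told apart from a response of these leaves to drought. A lower share of growing cells stays open too, untested. Markers of dividing cells fell in 5 of 11 probe sets, but so did 2211 of all 6308. Relative to all probe sets their median was -0.32, with PCNA and CYCD3 at -1.18 and -1.13. The ribosomal list has 6 probe sets of 5 genes and its call is lost with an estimated correlation, so other ribosomal protein genes stay open. Intact RNA and counts of dividing cells from the same leaves would test this.

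Higher both in unstressed CBF1OX plants and in WT at 4 °C were 43 probe sets. Probe sets that are easily called in any comparison would overlap as often after shuffling within classes of signal and SE. From the shuffles 26.1 were expected (SD 4.6, highest 46), and a share of 5e-04 of 10000 reached 43. The shuffles treated probe sets as independent, while genes can move together. Both comparisons also take their SE from the same fit, which broad classes even out only in part. The share may therefore be too low, and easily called probe sets are not excluded. A candidate explanation is that the transgene acts on part of the cold-responsive genes without cold. Of 954 probe sets higher in WT at 4 °C, 43 were called higher in these CBF1OX plants, as were 165 of all 6308. Of 676 lower at 4 °C, 34 were called lower in them, as were 272 of all 6308. Groups of 2 arrays miss many changes, so these are shares of calls and not of genes moved. The correlation of the 2 effects across all probe sets was 0.088. Inside the low temperature experiment the CBF1OX effect and the WT cold response share the WT control arrays, which alone makes them covary. There the covariance was 0.053 (r = 0.103), against a mean of 0.049 in 100 simulations with no effect. That experiment thus gave almost no covariance beyond the shared arrays, with a difference of 0.004.

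The difference between CBF1OX and WT without stress was set against other splits of the 8 control arrays into groups of 4. Of 34 splits that could be fitted, 1 gave as many probe sets, the real one, with 899, and the highest other gave 1. This argues against chance in the grouping of these arrays but does not exclude it, as only 34 splits were available. The other splits also keep the genotype difference in their residuals, which lowers their counts. Differences between plants are not reached, since the labels do not say whether the arrays of a group came from separate ones. The remaining split followed the 2 experiments and could not be fitted.

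The response to low temperature differed between the genotypes in 6 probe sets by the test of the interaction, in 42 after quantile normalization, in 45 with an offset of 16 and in 28 with the arrays of the experiment alone. HT2 differed by 3.62 as measured and at least 3.34 against background (CBF1OX 2.85; both WT arrays at 4 °C below background), and lost its call without any array but WT control B and WT low temperature A (highest adjusted p = 0.103). The count was 11 without WT low temperature array A, 1 without CBF1OX control array B and 2 without CBF1OX low temperature array A. In 4 unnamed probe sets the differences were 2.33, -1.08, -1.77 and -2.83, which kept their calls in 6, 7, 7 and 13 of 15 alternatives (highest adjusted p = 0.176, 0.139, 0.139 and 0.0772); for a further one -5.15 was measured (adjusted p = 0.00226), but all 4 WT arrays lay below background, so its size cannot be read; it kept its call in all 15, and in CBF1OX it stood at -1.69. The response to high light differed in 2 probe sets, AgpL1 by 2.32 (WT 1.09, a call lost without array B of either WT group; CBF1OX 3.41) and an unnamed one by 1.45 (WT 0.30, CBF1OX 1.75, adjusted p = 0.0355; kept in 7 of 15 alternatives, highest adjusted p = 0.167). The call of AgpL1 held without WT high light array B and with no other array left out (highest adjusted p = 0.167), and 0 probe sets passed without WT control array B, either CBF1OX control array or CBF1OX high light array A.

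Among the 63 reporter control probe sets, which the comparisons do not use, 1 had a signal of at least 1027.7 on every CBF1OX array and of at most 20.5 on every WT array. Between CBF1OX and WT controls it differed by at least 7.43 on the log2 scale (adjusted p = 2.58e-08), as all 4 WT arrays lay below background.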

How the results depend on the processing

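Centring of arrays on their median was chosen only after the data were seen; the other alternatives were planned. Of 417 values of named genes, 376 passed the threshold, 251 of them under every alternative and 254 whichever single array was left out. Over 4732 alternatives of these values, 4232 kept their side of the threshold, 463 no longer passed and 36 newly passed. Of values past the threshold 1 reversed: PsbQ in drought, 0.12 (0.116) after quantile normalization. Changes of sign in values that had not passed were counted as kept. In drought these included DREB3 (-0.32 as measured, 0.08 after quantile normalization) and CAB6A (-0.18 and 0.06). Of 186 counts and other values of comparisons under alternatives, 143 stayed and 43 moved, where a count stayed within 1.5 times and the correlation of the CBF1OX effect with the cold response within 0.062, the SD of r over single arrays (0.088 as reported, 0.033 to 0.134 under alternatives). After an array is left out, the lone array of its group is assumed to vary like the other groups. Signal over background limits what dim probe sets can show: folds against groups below a background of 9.8 to 35.3 are lower bounds, and CBF1, DREB1, DREB2 and TAS14 could not be tested. Except where fewer arrays show it, the cause was not tested.

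After quantile normalization, 657 probe sets differed between CBF1OX and WT controls of the high light experiment (437 as reported), 42 passed the low temperature interaction and 1 the high light interaction. With the arrays of its own experiment alone these were 662, 28 and 0 (435 at an unadjusted p under 0.05). Centring gave 36 and 1 for the interactions, an offset of 16 gave 45 for low temperature, and no filter gave 3. Of 27 list calls, 0 held with an estimated correlation, and fry made 43 calls. With the replicate letter as a replicate block, the low temperature interaction counted 30; the letters did not pair the arrays (r from -0.071 to 0.181, above 0.1 in 1 of 13 pairs of groups), so this value is not preferred.

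With 1 array left out, counts ran from 925 to 1219 for WT low temperature, 839 to 1177 for WT high light and 880 to 1134 for CBF1OX high light. For CBF1OX against WT they ran from 166 to 275 and from 156 to 232 in the controls of the low temperature and high light experiments, from 266 to 533 at 4 °C and from 124 to 257 in high light. The interactions ran from 1 to 11 and from 0 to 5, and the overlap of the 3 stresses from 53 to 88. In drought the count ran from 2239 to 2570.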

Other observations

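The lists of this part were added from the symbols of the array before any test, and no test here was chosen only after the result was seen.

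In the list of carotenoid and plastid isoprenoid synthesis, 6 of 14 probe sets rose in WT high light and 1 fell (7 and 1 adjusted over the list alone). The relative median was 0.65 (camera adjusted p = 0.000325, and adjusted p = 0.499 with an estimated correlation). The list is not of synthesis alone, as it also holds the cleavage enzyme CCD1A. Relative to all probe sets, ChrC rose by 1.86, the lycopene cyclase LCY1 by 1.65, the plastid terminal oxidase PTOX by 1.63 and the carotenoid cleavage dioxygenase CCD1A by 1.31. In CBF1OX 5 of 14 rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.00191; adjusted p = 0.439 with an estimated correlation). At 4 °C the phytoene synthase Psy1, the entry step of carotenoid synthesis, rose by 3.37 in WT and 4.54 in CBF1OX, in a list with 4 higher and 1 lower of 14 in WT. In drought 3 were higher and 2 lower, and 7 higher and 0 lower after quantile normalization.

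Photoreceptors and light signalling genes fell in high light in 5 of 9 probe sets in each genotype, also adjusted over the list alone. As measured, the blue light receptor genes CRY2 and CRY1A fell in WT by -1.30 ± 0.20 (adjusted p = 0.000101) and -1.14 ± 0.21 (adjusted p = 0.000707), and in CBF1OX by -1.25 and -1.21. For the list camera gave an adjusted p = 0.128 in WT (adjusted p = 0.639 with an estimated correlation) and an adjusted p = 0.0199 in CBF1OX (adjusted p = 0.474 with an estimated correlation). At 4 °C 1 of 9 rose and 2 fell in WT, in drought 1 was higher, and without stress 2 were higher in CBF1OX than in WT.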
